A study of Mus musculus with 24 samples.

How the data were processed

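Cortical collecting ducts (CCDs), the last tubule segment of the renal cortex, were microdissected from male C57BL/6 mice, and each library held the polyA RNA of 1 tubule. Per the labels' protocols, RNA was extracted with a Zymo kit, cDNA was made with the SMART-Seq V4 low-input kit, and sequencing was on an Illumina NovaSeq instrument. The labels name 4 wild-type (WT) mice and 4 mice with a mutant beta-catenin (MUT), with 3 tubules per mouse, 24 libraries in all. The treatment field of the labels reads vehicle, while their treatment protocol describes untreated groups, and no treatment was compared here. The labels' protocols give the mutant as Thr551Ala and Ser552Ala, and the legend of the deposited table names only the second change, so the alleles are called MUT throughout.

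The authors deposited 1 table of TPM, a transcript abundance scaled for gene length and library size, for 55416 genes, with gene symbols. The submitters' processing notes name STAR, RSEM 1.3.3 and the genome build GRCm39, with no role or order. The version printed there for STAR was left out because it is not a version of that tool. The annotation release and any filter are not given in the sources used here. The TPM of every library summed to the same fixed total within rounding, so the deposited values keep no sequencing depth, and no interval or detection limit that needs depth is given. The number of genes above 0 TPM ran from 23580 to 32480 per library, and the number at 1 TPM or more from 13572 to 16091. The authors' deposited p-value per gene equalled a two-sided equal-variance Student test of TPM over the 12 WT and 12 MUT libraries to within 9.3e-13, which treats the 3 tubules of a mouse as independent. In 11888 genes at 0 in every library that column held a spreadsheet error. The authors' mean and ratio columns were not used. Of the table's genes, 1705 shared a symbol with another row, and the row with the highest mean TPM kept the symbol.

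The mouse was the replicate. TPM were transformed as log2(TPM + 1), the 3 tubules of each mouse were averaged on that scale, and genes with a mean of at least 1 TPM over the libraries were kept, which left 15013. The 4 MUT mice were compared with the 4 WT mice by limma 3.58.1 in R 4.3.3, with empirical Bayes moderation, a mean-variance trend and no covariate. Benjamini-Hochberg adjustment and a threshold of 0.05 were used. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes, and are given as MUT minus WT with the limma standard error (SE). Levels are means ± SD over the 4 mouse means. The mice are separate animals by number, and nothing in the labels says whether genotypes were littermates or were dissected on shared days.

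Before the data were examined, 37 gene lists were fixed for cell types, signalling and general cell states. The 34 lists with at least 5 tested genes were compared with the other genes by limma's camera with a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way, were the alternatives. Each list has also the number of members past the threshold when p was adjusted over the list alone. That number takes no account of the other lists, and members that vary together are not separate findings. The markers of 9 cell types other than principal and intercalated cells were scored as the mean log2(TPM + 1) per mouse and compared by a two-sided exact permutation test over the 70 arrangements of 8 mice, whose smallest possible p is 0.029. The likeness of tubules of 1 mouse was tested one-sided by permuting mouse labels within genotype 100000 times. Other alternatives were pseudocounts of 0.1 and 5, no filter or a filter at 10 TPM, median-ratio scaling, quantile normalization and averaging tubules as TPM. Further ones were the 24 libraries with the mouse as a random effect or as independent, array weights, the mouse number as a block, and leaving out each mouse and each library.

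The genes named in the text follow a rule fixed beforehand. Ctnnb1, Aqp2 and Avpr2 were always given, then genes past the threshold. Because none passed, the rule gave for each direction the 5 genes with the smallest unadjusted p among those whose MUT and WT mouse means did not overlap. For each list it gave the 2 members with the highest mean TPM or the 2 with the smallest p. Some of these genes and 1 of the lists past the threshold are not reported here. The limma and list steps were tested on simulated data made from the real means and the real spread between mice and tubules of the 15013 genes. Of 50 genes changed by 1 log2 unit, 78% were recovered, and of 50 changed by 0.5 units, 28% were, with 2 false calls among 156. In the simulation 200 genes were changed at once, which eases the adjusted threshold. These shares therefore overstate recovery where few genes differ. Genes were drawn independently in the simulation, so it does not show how camera behaves when genes of a list vary together. Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used to read the table and draw figures. A RefSeq gene table of assembly GRCm38.p6 served only for the order of genes around Ctnnb1. No coordinates are printed because no annotation of the submitters' build was used here.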

Results

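Single-tubule RNA-seq was used to ask how the transcriptome of the CCD depends on 2 neighbouring residues of beta-catenin, threonine 551 and serine 552, that the mutation replaces with alanine per the labels. Transcript levels were measured as TPM in 24 microdissected tubules, 3 from each of 4 WT and 4 MUT mice. Depth is unknown because TPM keeps none. Paired values without a group are given for WT first and MUT second. In each library the 10 most abundant genes took 7.57% to 9.49% of all TPM. The number of genes above 0 TPM averaged 28376 ± 2328 in WT and 29767 ± 945 in MUT mice (SD, n = 4 each, exact permutation p = 0.371).

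Beta-catenin mRNA differed between genotypes by less than the spread between mice. Ctnnb1, which encodes beta-catenin, the Wnt effector and adherens junction protein, was at 387 ± 11.9 TPM in WT and 383 ± 16.7 TPM in MUT mice (SD, n = 4 each, log2 difference -0.01, SE 0.05). The mutation changes amino acids, so this level does not check the genotype labels. Aqp2, the vasopressin-regulated water channel of principal cells, was at 17257 ± 7155 TPM in WT and 15649 ± 4642 TPM in MUT mice, a log2 difference of -0.10 (SE 0.28). Avpr2, the vasopressin V2 receptor, was at 1033 ± 315 and 1055 ± 193 TPM, a log2 difference of 0.06 (SE 0.20).

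The 2 genes with the smallest p lay in opposite directions, and neither passed the threshold. Anp32a, which encodes an acidic nuclear phosphoprotein, was at 50.5 ± 5.23 TPM in WT and 26.7 ± 3.51 TPM in MUT mice (log2 difference -0.89, SE 0.11), and lower in 4 of 4 MUT mice than in any WT mouse. S100a14, a member of the S100 family of calcium-binding proteins, was at 14.4 ± 1.83 TPM in WT and 25.4 ± 3.06 TPM in MUT mice (log2 difference 0.82, SE 0.10), and higher in 4 of 4. Both had a limma adjusted p of 0.165. The other genes that the rule gives with higher values in MUT were Commd1b (log2 difference 2.49, SE 0.45), the mitotic kinase Aurkb (0.88, SE 0.16), the DNA topoisomerase Top2a (0.79, SE 0.15) and the ubiquitin-conjugating enzyme Ube2e1 (0.24, SE 0.05). Commd1b is a near copy of Commd1, so its value is uncertain. Those with lower values were the glycosyltransferase gene B3gnt2 (-0.29, SE 0.06), Pakap (ENSMUSG00000089945, a symbol that more than 1 gene of the table carries, -0.27, SE 0.06), Dus4l (-0.62, SE 0.14) and Cdkn1b, which encodes the cell cycle inhibitor p27 (-0.69, SE 0.16). These 8 genes all had a limma adjusted p of 0.869.

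**Figure D1:**
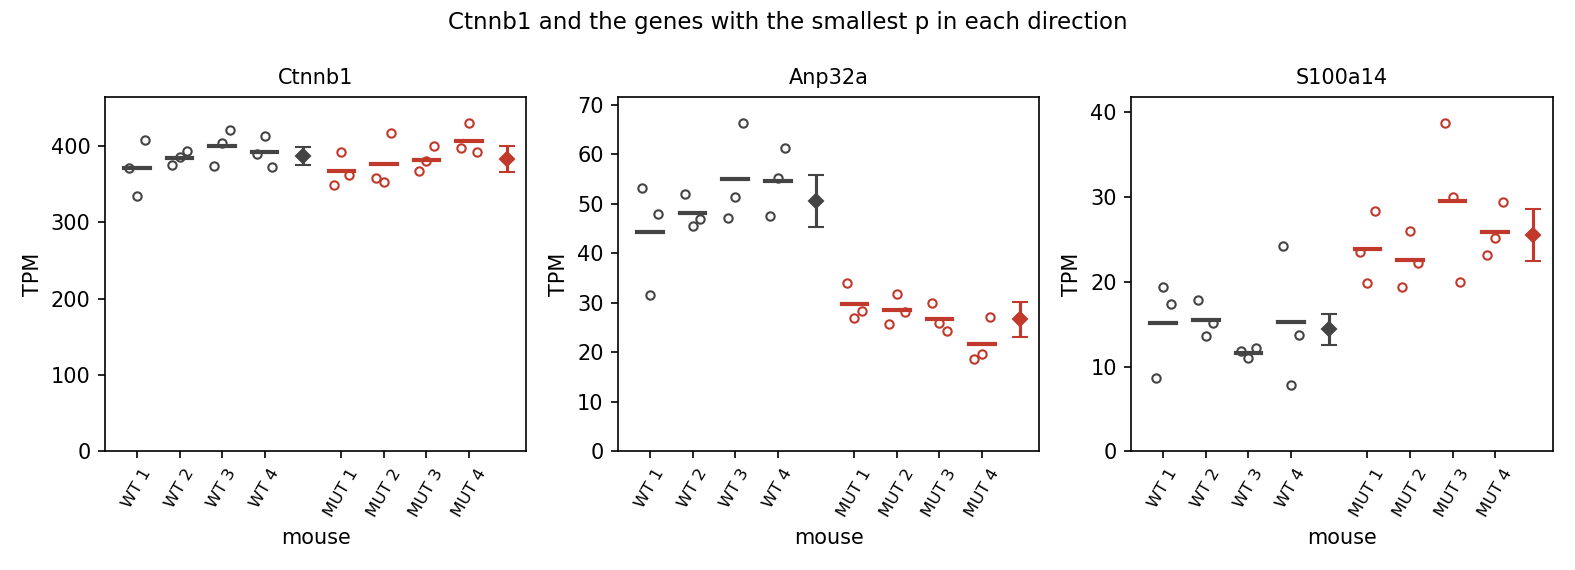
TPM of Ctnnb1, Anp32a and S100a14 (y axes) in each tubule library (circles) by mouse (x axis), with the mean of each mouse (bars) and the mean ± SD over the 4 mice of a genotype (diamonds). All 4 MUT mice lie below the WT mice for Anp32a and above them for S100a14, while Ctnnb1 overlaps.

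No gene passed the threshold: limma called 0 of 15013 genes, and 691 had an unadjusted p under 0.05 (423 higher and 268 lower in MUT) where chance alone gives 751. Without WT mouse 2 that number was 1153, again with 0 past the threshold. After median-ratio scaling the number was 685, with 357 higher and 328 lower. The 4 MUT mice lay all above the 4 WT mice in 291 genes and all below in 162, 3.02% of genes where chance gives 2.86%. The median absolute log2 difference was 0.08 and the median SE 0.11. When the 24 libraries were fitted with the mouse as a random effect, limma called 1 gene, Anp32a (adjusted p = 0.00141), and when they were taken as independent it called 28. Over the unblocked alternatives the limma adjusted p of Anp32a ran from 2.95e-05 to 0.948. By the authors' deposited table, 2849 of 43528 genes had p under 0.05, where limma with no filter gave 1554 over as many genes. After Benjamini-Hochberg adjustment 11 genes of the deposited table passed. Of these, 10 were tested in the main fit, and all 10 had an unadjusted p under 0.05 without passing the threshold. They were picked by their p in the same libraries, so a low limma p was likely beforehand and is no separate support.

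Proliferation genes rose in MUT tubules by a mean of 0.45 on the log2 scale, with 17 of 18 tested members higher (camera adjusted p = 5.31e-13, and adjusted p = 0.174 with an estimated correlation). With fry the adjusted p was 0.0427. By limma 0 members passed over all genes, and 8 did, all upward, when adjusted over the list alone. Aurkb was at 2.02 ± 0.310 TPM in WT and 4.34 ± 1.01 TPM in MUT mice, and Top2a at 2.41 ± 0.472 and 4.57 ± 0.872 TPM. Cdk1, the mitotic cyclin-dependent kinase, was chosen after its values were seen and was at 4.14 ± 2.14 and 9.29 ± 1.73 TPM (log2 difference 1.26, SE 0.27). The DNA replication clamp gene Pcna was at 36.5 ± 1.28 and 41.3 ± 2.96 TPM, and Tyms, for thymidylate synthesis, at 67.1 ± 9.08 and 65.7 ± 13.5 TPM. The 8 mitotic members had a mean log2 difference of 0.77 and the 10 members of DNA synthesis and the G1/S step one of 0.20. The 8 are the tested members left once the 10 were set apart. This split was not part of the fixed lists and was not tested. The score of the 20 fixed genes was 2.66 ± 0.140 in WT and 3.12 ± 0.182 in MUT mice (mean log2(TPM + 1), SD, n = 4), with 4 of 4 MUT mice above every WT mouse (two-sided exact permutation p = 0.029, the smallest possible, not planned for this list and not adjusted). The mean difference was 0.11 where only members at 10 TPM or more were kept, 0.23 at a pseudocount of 5 and 0.68 at 0.1. It was 0.59 without the 7 libraries with high blood, proximal tubule or thick ascending limb markers, an alternative chosen after seeing the data. Endothelial markers also rose, by a mean of 0.21 (camera adjusted p = 0.0194, and adjusted p = 0.936 with an estimated correlation).

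**Figure D2:**
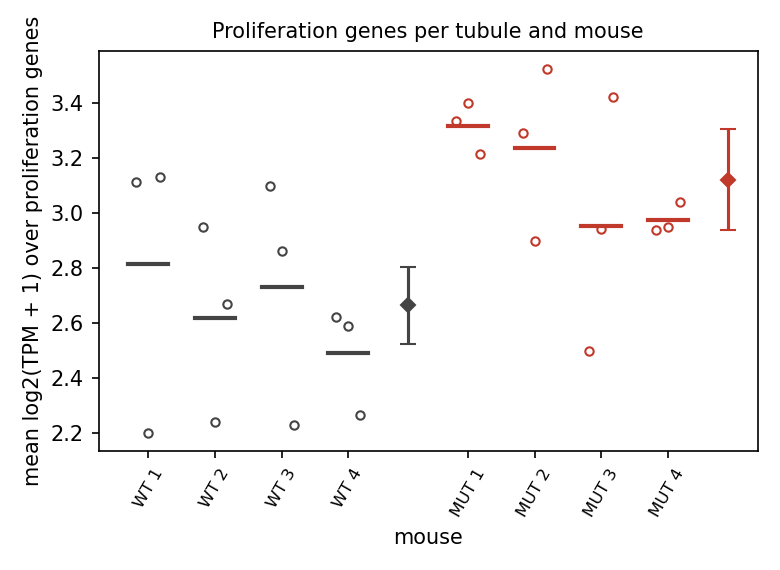
Mean log2(TPM + 1) over the 20 proliferation genes (y axis) in each tubule library (circles) by mouse (x axis), with the mean of each mouse (bars) and the mean ± SD over the 4 mice of a genotype (diamonds). The MUT mice average 3.12 and the WT mice 2.66, and single tubules overlap.

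Several other lists also moved by small amounts. The mitochondrially encoded genes rose by a mean of 0.24 over 7 tested members, all higher in MUT (camera adjusted p = 0.00441, and adjusted p = 0.826 with an estimated correlation). The complex I genes mt-Nd6 and mt-Nd2 were at 1188 ± 217 and 1404 ± 242 TPM in WT and at 1518 ± 216 and 1874 ± 395 TPM in MUT mice. Another 6 genes of this list were listed at 0 in all 24 libraries. Glycolysis genes rose by a mean of 0.10, with 15 of 15 higher (camera adjusted p = 0.00457, and adjusted p = 0.781 with an estimated correlation), among them Pgam1 (log2 difference 0.32, SE 0.08) and Pkm (0.10, SE 0.05). Cholesterol synthesis genes rose by 0.08, with 15 of 20 higher (camera adjusted p = 0.0205, and adjusted p = 0.826 with an estimated correlation), including the sterol oxidase gene Msmo1 (0.24, SE 0.08). Immediate early genes, which respond quickly to stimuli and to dissection, fell by 0.36 on the log2 scale, with 17 of 18 lower (camera adjusted p = 0.00800, and adjusted p = 0.936 with an estimated correlation). Fos was at 1441 ± 697 and 1060 ± 431 TPM and Junb at 1148 ± 566 and 932 ± 268 TPM. In these 4 lists 0 members passed by limma over all genes and 0 when adjusted over the list alone. The exact permutation test on mouse scores, not planned for these lists, gave an unadjusted p of 0.229 for mitochondrial and 0.171 for glycolysis genes. It gave 0.286 for cholesterol synthesis and 0.543 for immediate early genes. When the 8 mice were split 4 and 4 in other ways, camera called a median of 11 lists, so these camera calls do not set the genotypes apart. Without MUT mouse 4 the mean was 0.15 for the mitochondrial genes, 0.10 for glycolysis, 0.04 for cholesterol synthesis and -0.06 for immediate early genes, none past the threshold. With array weights the calls of the mitochondrial (0.14) and cholesterol genes (0.05) ended (camera adjusted p = 0.118 for both). Calls also ended without WT mouse 1 for glycolysis (0.06) and immediate early genes (-0.13). They ended without WT mouse 2 for the mitochondrial (0.12) and cholesterol genes (0.08). They ended without WT mouse 4 for cholesterol (0.06) and immediate early genes (-0.14), and for cholesterol also without MUT mouse 1 (0.05) or tubule 3 of WT mouse 4 (0.06). Without the 7 libraries with high erythrocyte, proximal tubule or thick ascending limb markers, the camera calls of glycolysis (mean 0.10, adjusted p = 0.0923) and immediate early genes (-0.13, adjusted p = 0.352) ended. Means that moved with the call kept were 0.15 for glycolysis without WT mouse 2, 0.12 for cholesterol synthesis without MUT mouse 3, and -0.57, -0.60 and -0.57 for immediate early genes without WT mouse 2, WT mouse 3 and MUT mouse 2.

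The Wnt and vasopressin lists, which bear on the mutated protein and on the main hormone of this segment, did not pass. Of 23 fixed Wnt/beta-catenin target genes, 11 were expressed enough to test, and 7 were higher and 4 lower (mean -0.05, median 0.04, camera direction down, adjusted p = 0.821). The cyclin gene Ccnd1 was at 108 ± 5.66 TPM in WT and 136 ± 33.6 TPM in MUT mice, and the Wnt feedback inhibitor gene Znrf3 at 7.33 ± 1.53 and 4.86 ± 2.64 TPM. Among Wnt pathway components 15 of 34 were higher (camera adjusted p = 0.460), with the co-receptor gene Lrp6 at a log2 difference of 0.21 (SE 0.08) and the receptor gene Fzd2 at -0.27 (SE 0.13). In the list for vasopressin, cAMP and protein kinase A, 13 of 25 were higher (adjusted p = 0.667), and Gnas, the stimulatory G protein subunit, was at 922 ± 29.4 and 912 ± 42.0 TPM. Vesicle trafficking genes for AQP2 recycling had 19 of 26 higher (adjusted p = 0.255), with the syntaxin gene Stx4a at -0.32 (SE 0.10) and the clathrin gene Cltc at 0.16 (SE 0.06). Adherens junction genes had 11 of 15 higher (adjusted p = 0.672), with Afdn at -0.20 (SE 0.07) and Cdh1, for E-cadherin, at 0.08 (SE 0.06). Tight junction genes had 12 of 16 higher (adjusted p = 0.261), with the claudin genes Cldn8 at 0.21 (SE 0.14) and Cldn7 at 0.02 (SE 0.08). In these 6 lists 0 members passed over all genes or when adjusted over the list alone.

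The cells of the duct itself also showed no difference past the threshold. Of 16 principal cell markers 12 were higher in MUT (camera adjusted p = 0.460), among them Fxyd4, a regulator of the sodium pump, at 5855 ± 1793 and 6514 ± 1628 TPM. Of 9 intercalated cell markers 6 were higher (adjusted p = 0.460), with the ammonia channel gene Rhcg at 2600.5 ± 175 and 2639 ± 121 TPM and the carbonic anhydrase gene Car2 at 2298 ± 72.3 and 2436 ± 113 TPM. Type A intercalated cell markers, including the anion exchanger gene Slc4a1 (451 ± 163 and 480 ± 84.4 TPM) and Kit (221 ± 14.8 and 232 ± 22.0 TPM), had an adjusted p of 0.357 by camera. Type B markers had one of 0.973, with the pendrin gene Slc26a4 at 1715 ± 349 and 1645 ± 195 TPM and Slc4a9 at 967 ± 149 and 960 ± 136 TPM. In these 4 lists 0 members passed by limma over all genes or when adjusted over the list alone. WT mouse 2 stood apart in the principal and type B scores, and without it the principal cell list (mean 0.23, adjusted p = 0.00449) and the type A list (0.29, adjusted p = 0.00940) passed.

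The other lists did not pass by camera, and 0 of their members passed by limma over all genes or when adjusted over the list alone. Their adjusted p was 0.0777 for endoplasmic reticulum stress, 0.172 for the osmotic response, 0.277 for heat shock, 0.348 for steroid-responsive genes, 0.458 for cytosolic ribosomal proteins and 0.460 for both DNA methylation and histone modifiers and the distal convoluted and connecting tubule markers. It was 0.562 for NF-kappaB and inflammatory genes, 0.583 for both p53 targets and extracellular matrix genes, 0.667 for nuclear respiratory chain subunits and 0.821 for the interferon response, tubule injury and leukocyte lists. Endoplasmic reticulum stress passed in 6 of 46 alternatives (no filter, or leaving out WT mouse 3, MUT mouse 2, MUT mouse 3, tubule 3 of WT mouse 2 or tubule 3 of MUT mouse 2), with means from -0.19 to -0.12 there. Leaving out 1 mouse or tubule also brought past the threshold heat shock genes (WT mouse 2, -0.24, or MUT mouse 2, -0.21) and ribosomal proteins (MUT mouse 4, 0.10, tubule 2 of MUT mouse 4, 0.05, or tubule 3 of WT mouse 1, 0.05). The same held for distal convoluted and connecting tubule markers (WT mouse 2, -0.52), extracellular matrix genes (WT mouse 3, -0.10), nuclear respiratory chain subunits (MUT mouse 1, 0.06) and leukocyte markers (MUT mouse 4, -0.31). Array weights also brought the ribosomal protein, leukocyte, and distal convoluted and connecting tubule lists past the threshold. Examples are the p53 target Bax (log2 difference -0.16, SE 0.05), the ribosomal protein gene Rpl6 (-0.16, SE 0.05), the cytochrome oxidase subunit gene Cox7c (0.36, SE 0.12), the guanylate-binding protein gene Gbp2 (0.63, SE 0.19), the chaperone gene Hspa5 (-0.38, SE 0.21) and the DNA methyltransferase gene Dnmt3a (-0.24, SE 0.09). Bax, Rpl6, Gbp2 and Dnmt3a went against most of their lists. Higher in MUT were 7 of 12 p53 targets, 55 of 82 ribosomal protein, 6 of 16 interferon response and 12 of 23 DNA methylation and histone modifier genes. Cox7c and Hspa5 went with theirs, with 44 of 79 respiratory chain and 5 of 17 endoplasmic reticulum stress genes higher. Mean and median differed in sign for tubule injury, p53 targets, extracellular matrix and DNA methylation, and camera went against the mean for tubule injury and against both for leukocyte markers.

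Erythrocyte, proximal tubule and thick ascending limb markers were detected in single tubules, with the highest sums in WT libraries. The haemoglobin genes Hbb-bs and Hba-a1 were at 1392 ± 2602 and 652 ± 1224 TPM in WT and at 12.3 ± 23.2 and 5.51 ± 10.0 TPM in MUT mice. The 5 erythrocyte markers fell by a mean of 2.36 on the log2 scale (camera adjusted p = 1.77e-09, and adjusted p = 0.375 with an estimated correlation), with 0 past the threshold by limma over all genes and 5 when adjusted over the list alone. The 15 proximal tubule markers fell by 1.02 (camera adjusted p = 2.27e-06, and adjusted p = 0.781 with an estimated correlation), with the androgen-regulated gene Kap at 533 ± 605 and 116 ± 93.0 TPM. The 6 thick ascending limb markers fell by 0.93 (camera adjusted p = 0.000648, and adjusted p = 0.781 with an estimated correlation), with the uromodulin gene Umod at 402 ± 364 and 51.7 ± 45.0 TPM and Egf at 190 ± 252 and 13.5 ± 14.5 TPM. In the proximal tubule and thick ascending limb lists 0 members passed over all genes or when adjusted over the list alone. All 9 tested endothelial markers were higher in MUT and the list rose by a mean of 0.21 (camera adjusted p = 0.0194, and adjusted p = 0.936 with an estimated correlation), with Plvap at 113 ± 46.1 and 125 ± 15.8 TPM and 0 members past the threshold over all genes or when adjusted over the list alone. That call ended without WT mouse 3 (0.08), WT mouse 4 (0.16), MUT mouse 3 (0.16) or MUT mouse 4 (0.18). It also ended without tubule 1 of WT mouse 1 (0.19), tubule 1 of WT mouse 2 (0.16), tubule 3 of WT mouse 3 (0.12), tubule 2 (0.18) or 3 (0.18) of WT mouse 4, tubule 2 of MUT mouse 1 (0.16), tubule 1 of MUT mouse 2 (0.17) or tubule 3 of MUT mouse 4 (0.16). With the 24 libraries fitted with the mouse as a random effect or as independent it ended too (camera adjusted p = 0.102 and 0.0733). It was kept without WT mouse 2 (0.34). By the exact permutation test on per-mouse scores, 0 of the 9 other cell types had a p under 0.05, unadjusted or adjusted. Since no p can be below 0.029, 1 type alone could not pass once adjusted over 9. The adjusted result therefore does not show that the genotypes were alike. The smallest p was 0.0571 for erythrocytes (adjusted p = 0.471), and the two-sided exact p was 0.229 for both proximal tubule and thick ascending limb, 0.314 for endothelial cells, 0.971 for leukocytes and 0.514 for fibroblasts and mural cells. It was 0.20 for podocytes, 0.286 for urothelium and 0.543 for the distal convoluted and connecting tubule. Erythrocyte marker sums reached 24918 TPM in tubule 2 of WT mouse 3, proximal tubule sums 7515 TPM in tubule 1 of WT mouse 3, and thick ascending limb sums 4851 TPM in tubule 1 of WT mouse 1. Without that last tubule the thick ascending limb mean was -0.44 (camera adjusted p = 0.0653), without tubule 1 of WT mouse 4 it was -0.61 and without WT mouse 2 -1.47. With tubules averaged as TPM it was -1.88 and the erythrocyte mean -3.87, and at a pseudocount of 5 the erythrocyte mean was -1.55. Without WT mouse 3 the proximal tubule mean was -0.55 (camera adjusted p = 0.0184). Without the 7 libraries in which 1 of these 3 sums passed 1000 TPM (5 WT and 2 MUT), the thick ascending limb mean was 0.43 (camera adjusted p = 0.449) and the endothelial mean 0.45, and too few erythrocyte markers were left to test. Distal convoluted and connecting tubule sums, not used for that choice, reached 4456 TPM in tubule 2 of WT mouse 1. They reached 3464 TPM in tubule 1 of MUT mouse 1, and both libraries were kept. Leukocyte sums, also not used, reached 1534 TPM in tubule 1 of WT mouse 1 and 1560 TPM in tubule 3 of MUT mouse 4.

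**Figure D3:**
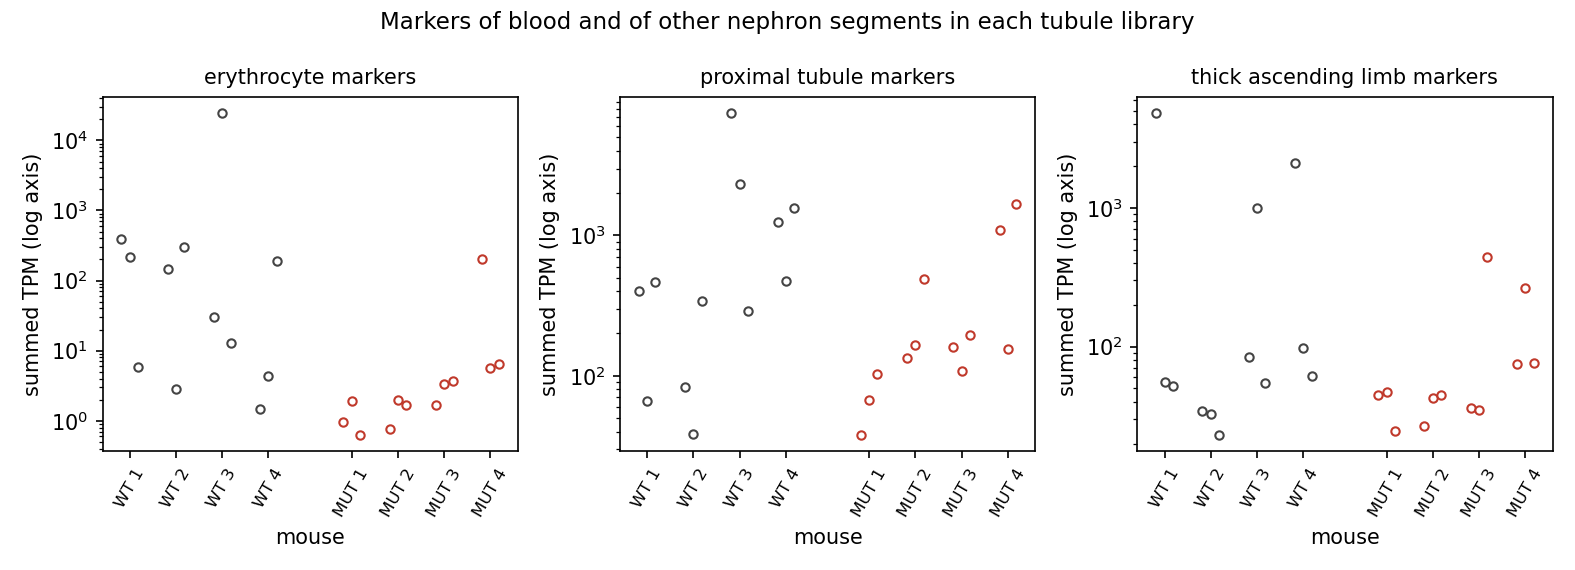
Summed TPM of erythrocyte, proximal tubule and thick ascending limb markers (y axes, log scale) in each tubule library (circles) by mouse (x axis). The highest sums, 24918, 7515 and 4851 TPM, are in WT libraries, and tubules of 1 mouse differ widely.

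Tubules of 1 mouse resembled each other slightly more than tubules of different mice. Across genes, the mean correlation of log2(TPM + 1) was 0.964 within a mouse and 0.958 between mice of the same genotype, a difference of 0.0062 (one-sided permutation p = 1e-05, the smallest that 100000 resamples can give). The estimated correlation of tubules within a mouse, over all genes, was 0.23.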

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

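The counts over other splits for the proliferation list and for the blood and segment markers, the comparison of proliferation with endothelial and leukocyte markers, and the correlations of markers between tubules were tests chosen only after the result was seen.

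Higher proliferation transcripts in MUT tubules may reflect more dividing cells, a biological explanation that the genotype groups allow. General behaviour of low genes is argued against, since the list's mean of 0.45 lay at percentile 100 of 10000 random lists matched on mean expression, whose highest was 0.27. Only 1 of the 35 splits of the 8 mice into 4 and 4, the real one, gave a shift as large (0.452, highest other 0.383), but 1 of 34 lists has its largest shift in the real split where chance gives 0.97, so chance over all lists is not excluded. Cells of another type cannot be told apart from this, because the proliferation shift exceeded the endothelial one by 0.243 (SE 0.24, exact permutation p = 0.429) and the leukocyte one by 0.437 (SE 0.60, exact permutation p = 0.486). Dissection day and litter are not in the labels and stay open.

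Lower blood, proximal tubule and thick ascending limb markers in MUT libraries could come from pieces of other segments or blood on single tubules. With the mean of each mouse removed, the markers of 1 type varied together over the 24 libraries, with mean correlations of 0.944 for erythrocyte, 0.636 for proximal tubule and 0.734 for thick ascending limb markers. Chance is not excluded for the difference between genotypes, since 2 of 35 splits gave an erythrocyte shift as large (2.36, highest other 2.47), 8 a proximal tubule shift (1.02, highest other 1.93) and 8 a thick ascending limb shift (0.928, highest other 1.74). An effect of genotype on these markers stays open and untested.

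The lower Anp32a and higher S100a14 values may be chance, since 19 of 35 splits had a smallest p as small (2.18e-05, smallest other 1.39e-07). Reads moved from Anp32a to the 4 paralogs and pseudogenes with an Anp32 symbol are argued against, if their lengths are like that of Anp32a. Those 4 together were higher by 2.58 TPM (SE 3.78) where Anp32a was lower by 23.8 TPM. TPM are scaled for gene length, and copies without such a symbol were not summed, so a move of reads to other copies is not excluded. Alleles of another strain near the edited gene cannot be told apart from an effect of the mutation for Anp32a, which lies on chromosome 9 with Ctnnb1. Of 89 tested neighbours of Ctnnb1, 6 had an unadjusted p under 0.05 against 4.59% of other genes (Fisher's exact p = 0.305, odds ratio 1.5, 95% interval 0.534 to 3.43). That test took at most 50 genes on each side, and Anp32a lies 337 tested genes away, so it cannot decide for Anp32a. S100a14 lies on chromosome 3, so alleles beside Ctnnb1 are argued against as a direct cause for that gene.

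The real split gave 0 genes past the limma threshold (691 at an unadjusted p under 0.05, and 1 and 28 genes with the 24 libraries fitted with the mouse as a random effect and as independent). All 35 of 35 splits reach a count of 0, so this count says nothing on chance, and the highest other split gave 48. As many genes at an unadjusted p under 0.05 came from 17 of 35 splits (691, highest other 1921), and as many lists from 22 of 35 (10, highest other 20). Chance is excluded for neither of these 2 counts.

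In 20 of 212 groups of 4 mice, 1 mouse lay far from the others. Chance gives about 1 in 20 for independent groups of normally distributed values. These groups share mice and related genes, and gene values were untransformed TPM, so the 2 rates cannot be compared strictly. WT mouse 3 was at 11.65 TPM for S100a14 (others 15.11 to 15.5), 2488 for Hba-a1, 5295 for Hbb-bs, 2406 for Car2 and 198.7 for Kit, with an extracellular matrix score of 4.121. MUT mouse 4 was at 20.56 TPM for Hba-a1, 47.19 for Hbb-bs, 2459 for Rhcg (others 2679 to 2711) and 1162 for Slc4a9, with an erythrocyte score of 1.907 and a ribosomal protein score of 6.402. Erythrocyte sums were high in 1 tubule of each of these 2 mice. In WT mouse 3 they were 24918 TPM in tubule 2 against 30.5 and 12.7 TPM in tubules 1 and 3. In MUT mouse 4 they were 203 TPM in tubule 1 against 5.74 and 6.51 TPM in tubules 2 and 3. MUT mouse 1 was at 2268 TPM for Car2, 264.9 for Kit and 124.5 for the taurine transporter gene Slc6a6, with a nuclear respiratory chain score of 9.051. WT mouse 2 was at 36.74 TPM for Lrp6, with scores of 9.804 for principal cell, 8.486 for type B intercalated cell and 3.571 for distal convoluted and connecting tubule markers.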

How the results depend on the processing

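The alternative without the 7 libraries high in erythrocyte, proximal tubule or thick ascending limb markers was chosen only after the data were seen. Of 7929 alternative values of 187 results, 7846 were labelled unchanged, 55 weaker, 27 stronger and 1 reversed. The reversed one was the thick ascending limb mean (0.43 without the 7 libraries). Each tested value was labelled by a gained or lost call, and each count of genes, lists or cell types by how far it moved. The sign differed in 289 values of 61 results, of which 286 were not past the threshold in either setting. For leukocyte markers the mean was 0.02, and -0.42 with array weights and -0.31 without MUT mouse 4, both past the threshold. The number of genes past the limma threshold was 0 (691 at an unadjusted p under 0.05) and stayed 0 except with the mouse as a random effect (1) and with 24 independent libraries (28), a fit that takes the 3 tubules of a mouse as separate animals. The lists past the threshold numbered 10, against 0 with an estimated correlation, 1 with fry, 6 without the 7 libraries, and 7 to 12 with a mouse or tubule left out. The number of other cell types past the threshold after adjustment was 0 throughout, a count that the smallest possible p nearly fixes. Without WT mouse 4, 1 cell type had an unadjusted exact permutation p under 0.05. The likeness difference was 0.0047 to 0.0071 with a mouse left out and 0.011 at a filter of 10 TPM. With the mouse number as a replicate block, limma called 0 genes (483 at an unadjusted p under 0.05) and camera 10 lists. The values gave no sign that the numbers pair the mice. Same-numbered mice had correlations of their deviations of -0.02, 0.02, -0.04 and 0.01, and no WT mouse correlated best with the MUT mouse of its own number. These correlations cannot exclude shared litters or dissection days. The sign-flip test with that block cannot go below 0.125. Without the 7 libraries, and at a filter of 10 TPM, the erythrocyte list had too few tested genes to give a value, as had the thick ascending limb and the distal convoluted and connecting tubule lists at that filter. The cause of the other changes was not tested, and TPM keep no depth from which a limit could be given.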

Other observations

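The relations between cell type scores were tests chosen only after the result was seen.

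Mitotic genes outside the fixed lists were looked at as a separate group of 35, chosen before their values were seen, of which 28 could be tested. In MUT mice 26 of 28 were higher, with a mean log2 difference of 0.378, and the score was 1.82 ± 0.206 in WT and 2.20 ± 0.268 in MUT mice (SD, n = 4 each, two-sided exact permutation p = 0.114). By limma 10 had an unadjusted p under 0.05, 0 passed over all genes and 0 when adjusted over the list alone. By camera the unadjusted p was 2.56e-11, and 0.0777 with an estimated correlation. The hypothesis that transcripts of dividing cells are more abundant in MUT tubules cannot be told apart from no difference by this test, since the highest WT mouse (2.02) lay above the lowest MUT mouse (1.91).

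Mice of both genotypes differed in the balance of principal and type A against type B intercalated cell markers. The relations were tested over all 8 mice and not within a genotype. Over 8 mice the principal and type B scores had r = -0.97 (permutation p = 0.000273, adjusted over 3 relations by Benjamini-Hochberg 0.00041) and rho = -0.905 (permutation p = 0.00456, adjusted 0.00456), with r = -0.891 without WT mouse 2 and MUT mouse 1. The type A and type B scores had r = -0.90 (permutation p = 7.44e-05, adjusted 0.000223) and rho = -0.976 (permutation p = 0.000397, adjusted 0.00119), with r = -0.975 without WT mice 2 and 3. The principal and type A scores had r = 0.877 (permutation p = 0.00211, adjusted 0.00211) and rho = 0.929 (permutation p = 0.00223, adjusted 0.00335), with r = 0.653 without WT mouse 2 and MUT mouse 1. A candidate explanation, as a hypothesis, is that tubules were taken from different positions along the duct, and the positions are not in the labels. The scores come from TPM with a fixed total, so more of 1 cell type can lower the others. Any change in cell mix could therefore give such relations, and they cannot decide for position.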
